A study of Daphnia magna with 40 samples.

How the data were processed

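RNA of whole Daphnia magna was measured on 40 one-colour Agilent arrays, 4 for each of 10 groups. The groups combined 2 stages with 5 treatments, taken from the stage and treatment labels. Per the labels' protocols, total RNA was purified on columns, amplified and labelled with the dye Cy3. Per the labels' protocols, juvenile exposures were set up in 4 separate vessels per treatment, each giving a pool of 20 animals. For adults the labels state neither how many females made a sample nor how the replicates were kept, so adult p-values measure the spread between these samples, which may be partly technical.

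Per the file headers, the spots were quantified with Agilent Feature Extraction 10.7.3.1, and the scanner files hold intensity values per spot on a linear scale. The deposited processed intensity of each spot is already background-subtracted and detrended per the file headers. The deposited table of the whole series holds values on a log2 scale. Set against the scanner values of the same arrays, this table followed log2 signals that were quantile-normalized within each stage and centred on each probe's median over that stage. The correlation per array lay between 0.98 and 1 in adults and between 0.999 and 1 in juveniles. Its column medians ran from -0.0984 to 0.106 in adults and from -0.0713 to 0.0931 in juveniles. Any further step behind that table is not given in the sources used here. Because its rows were centred within a stage, it cannot give the difference between stages, and it served as an alternative for the other comparisons.

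Each array had 15744 spots, of which 15208 were not controls. They held 14338 probes, and 870 probes were spotted in duplicate. The main values were log2 of the processed signal minus the array's 75th percentile of it. Control spots and spots with an outlier mark of the scanner software were left out, saturated spots were kept, and spots of a probe were averaged. A probe was tested if it was well above background on at least 4 arrays of the fit. No array pair was a duplicate, the highest correlation between arrays being 0.9739. Precision is limited by the number of arrays per group.

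Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all tested probes of a comparison and an adjusted p under 0.05 as the threshold. Within a stage, the 20 arrays of its 5 groups entered a single fit and shared an estimate of the spread. The comparison of adult with juvenile acetone groups and the stage by treatment interaction used a fit of all 40 arrays. The interaction was a moderated F test over 4 terms, and each treatment's term was also tested singly. Differences between single measures of 4 and 4 arrays were tested with two-sided exact permutation tests, whose smallest possible p is 0.0286. The fit was tested on simulated data, drawn from a normal distribution with each probe's mean and residual SD of the real arrays. In the comparison of juvenile FV10 with acetone, on 12431 probes, it recovered 2% of probes changed by 0.5 on the log2 scale, 12% of those changed by 1, 58% of those changed by 2 and 96% of those changed by 3. For adult FX40 with acetone, on 11186 probes, the shares were 0%, 10%, 54% and 88%.

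The probes carried IDs and no gene names. The files do not pair the IDs with genes, and 0 of 14338 matched the gene table of assembly ASM2063170v1.1. None of the 25 gene lists therefore had a measured member, and neither camera nor fry could be run on them. Gene functions and genomic positions of the probes are not given in the sources used here. The rule for naming took, per comparison, the 10 probes with the largest rise and the 10 with the largest fall among those past the threshold whose 4 values in a group all lay beyond the 4 values of the other. It also asked for an informative gene name or description, and it added members of the gene lists. No probe carried such a name, so at most 2 IDs that were higher and 2 that were lower are given per comparison. Where a probe was saturated or not above background on arrays of a group, its change is uncertain in size.

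Arrays lay on 7 slides, and each slide had a single scan, so slide and scan are the same batch. Every slide held several groups, and values with slide as a block and within slides are given. Replicate letters recur between groups and were not treated as pairs.

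The groups, comparisons, tests, naming rule, gene lists and first set of alternatives were fixed before the data were examined. Those alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited log2 table, no filter on dim probes, only the arrays of the groups compared, the replicate letter as a block, slide as a block, and each array left out in turn. The normexp alternative was planned on mean signals. The files hold median signals, which were used in their place. Alternatives chosen after seeing the data were array weights, slide as a random block, the log2 75th percentile of the raw signal as a covariate, outlier spots kept, normexp with quantile normalization, juvenile FV10 arrays A and B left out together, and adult acetone arrays E and G left out together.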

Results

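Whole animals of Daphnia magna, a freshwater crustacean that reproduces clonally, were profiled as adults and as juveniles after exposure to selective serotonin reuptake inhibitors or nonylphenol. All came from clone F, a laboratory line. The arrays formed 10 groups of 4. In each stage these were the acetone carrier alone, fluoxetine at 40 µg/L (FX40), fluvoxamine at 10 µg/L (FV10), and nonylphenol at 20 µg/L (NP20) and at 60 µg/L (NP60). Fluoxetine and fluvoxamine are antidepressants that block the serotonin transporter, and nonylphenol is a breakdown product of surfactants. The doses are those of the sample labels. The text of the series gives 80 ppb for fluoxetine and 30 ppb for fluvoxamine, and the sources used here do not settle which applies. Juveniles were less than 1 day old at the start and were exposed for 3 days. Adults were gravid females, 8 to 9 days old at the start, exposed over 3 broods (10 to 14 days), and their eggs were flushed out before freezing. The series set out to test whether serotonin reuptake inhibitors disturb energy metabolism, juvenile development and offspring production.

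Signal strength differed between arrays. The 75th percentile of the raw processed signal ran from 76.9 to 484.6 intensity units in adults and from 204.7 to 773.6 in juveniles. Between 51.8% and 86.5% of probes were well above background on an adult array, and between 57.7% and 85.4% on a juvenile array. Of 14338 probes, 5029 were well above background on all 20 adult arrays, 6981 on all 20 juvenile arrays, 4331 on all 40 and 447 on none. Only 2 probes were well above background on every adult array and on no juvenile array, and only 1 the other way round. Probes are given by ID because the files do not pair them with genes.

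Fluvoxamine in juveniles was compared with acetone. Of 12879 tested probes, 1020 differed between FV10 and acetone in limma, 676 higher and 344 lower, with a median change of 1.51 on the log2 scale in either direction. The change was at least 2-fold for 640 of the higher and 246 of the lower probes. The 4 FV10 values lay beyond the 4 acetone values for 419 of the higher and 295 of the lower probes. Over all tested probes with complete values 11.8% did not overlap, where chance gives 2.86%.

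DM09934P1 changed most. It was higher in FV10 juveniles, at 6.48 ± 1.94 (SD, n = 4) against -0.84 ± 0.87 (SD, n = 4) in acetone on the scaled log2 axis (log2 change 7.32, SE 0.82, adjusted p = 0.000636). DM14640P2 rose by 3.48 (SE 0.58, adjusted p = 0.0138), or 0.94 with normexp correction, and was well above background on 3 of 4 acetone arrays. DM06523P3 was lower, with a log2 change of -4.53 (SE 0.74, adjusted p = 0.0138). It was well above background on 3 of 4 FV10 arrays, so the size of the fall is uncertain, and normexp correction gave -2.43. DM14198P1 also fell, with a log2 change of -4.03 (SE 0.95, adjusted p = 0.0237). These 4 probes were picked among those whose groups did not overlap. DM09934P1 kept an adjusted p under 0.05 in every alternative run. Its log2 change was 6.72 without FV10 A, 8.03 without FV10 C, 5.68 without both A and B and 5.65 with brightness as a covariate. Without FV10 A the adjusted p was 0.0613 for DM14640P2, 0.0613 for DM06523P3 and 0.0888 for DM14198P1, and without FV10 B it was 0.0631, 0.0631 and 0.0893. For DM14198P1 it was also 0.0698 without acetone A and 0.0689 without acetone C. The changes of these 3 probes kept their direction under all alternatives, and they missed the threshold with slide as a block, with brightness as a covariate and after normexp correction.

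**Figure D1:**
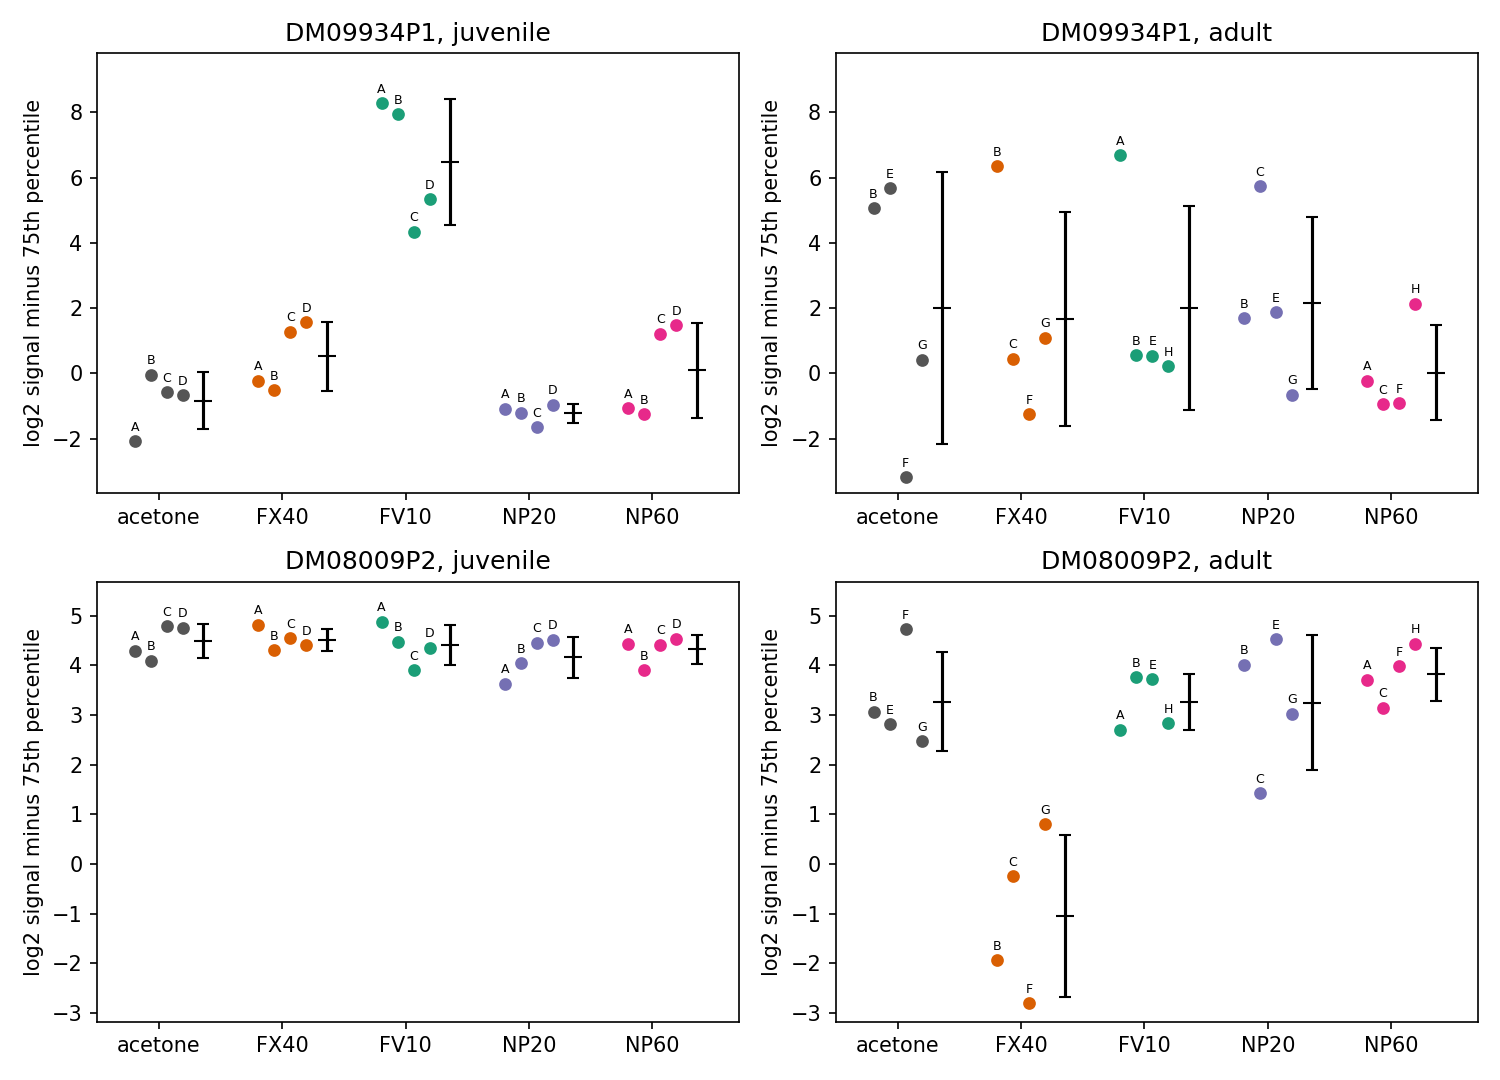
Scaled log2 signal of DM09934P1 (top) and DM08009P2 (bottom) in juveniles (left) and adults (right), by treatment; each point is an array with its replicate letter, and the bar gives the mean and SD of 4 arrays. DM09934P1 lay between 4.34 and 8.28 in FV10 juveniles and at 1.56 or less on the other juvenile arrays, and DM08009P2 lay between -2.80 and 0.81 in FX40 adults.

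The count of 1020 depended on single arrays and on how slide entered the fit. FV10 arrays A and B stood apart from the rest of the juveniles on the leading principal component (21% of the variance), at scores of 126.5 and 90.9, where arrays C and D lay at -6.2 and 21.7. Without A the count was 3, without B 2, without C 2481, and without acetone A, C or D it was 110, 156 or 407. Without both A and B it was 4. FV10 arrays were dimmer than acetone arrays, at a log2 75th percentile of 8.07 ± 0.47 (SD, n = 4) against 8.88 ± 0.50 (SD, n = 4; exact permutation p = 0.0857, adjusted over 8 comparisons 0.304). With this brightness as a covariate 4 probes were called, and the median change of the 1020 probes went from 1.51 (median SE 0.381) to 1.01 (median SE 0.426). With slide as a block 1 probe was called and the median change was 1.43 (median SE 0.425). With slide as a random block 1023 were called, including all 1020. FV10 and acetone arrays met on slides 6 and 7. When 1020 probes were picked without the arrays of the slide, they differed within it by a median of 0.189 in the picked direction on slide 6 (C against acetone D, 60% of probes) and of 1.6 on slide 7 (B against acetone A, 94.9%), against 1.82 and 1.38 in the arrays used to pick them. With only the 8 arrays of both groups in the fit 5 probes were called, and with normexp correction 1. The direction split also depended on scaling. The median of all tested probes was 0.195 after scaling to the 75th percentile and -0.0306 after quantile normalization, which called 449 higher and 528 lower, and the deposited log2 table gave 499 higher and 534 lower.

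**Figure D2:**
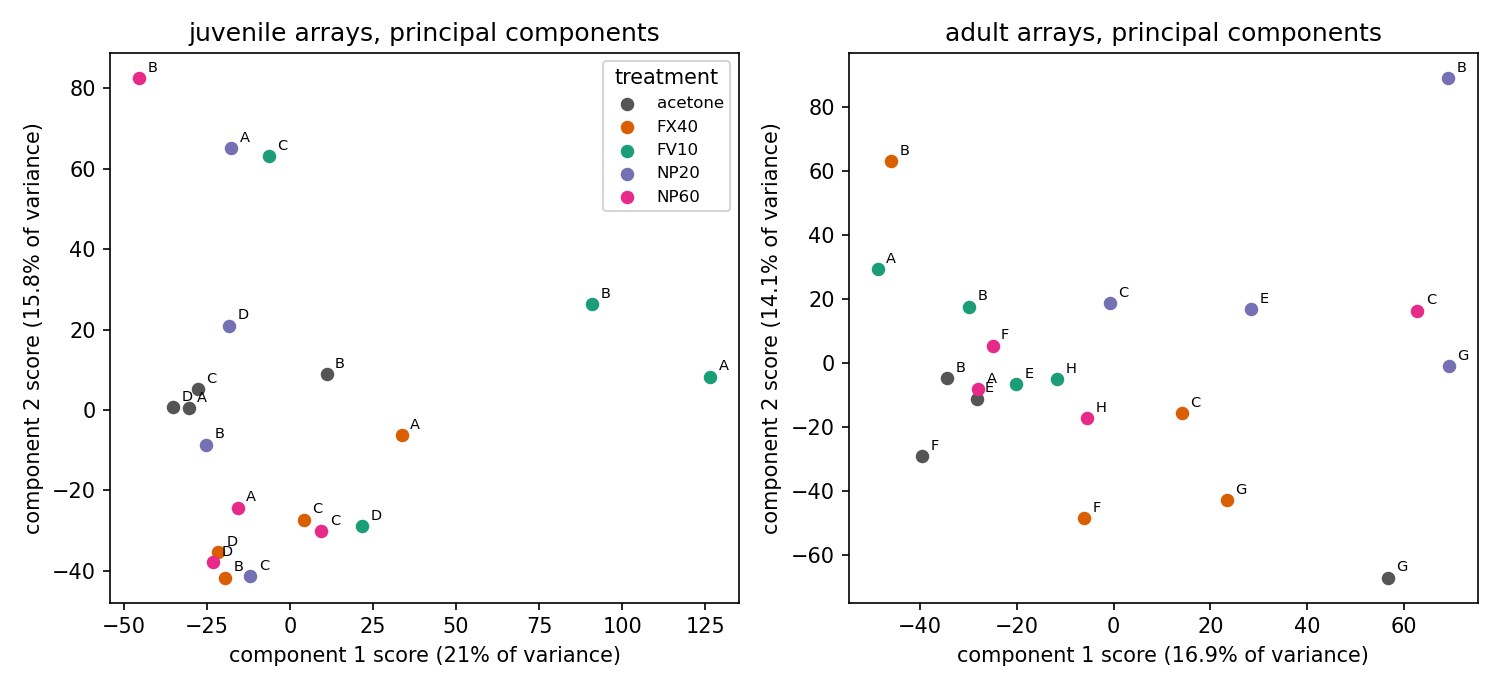
Scores of the 20 juvenile arrays (left) and 20 adult arrays (right) on the 2 leading principal components of the scaled log2 signals, coloured by treatment, with replicate letters. Juvenile FV10 arrays A and B had the highest scores on the leading juvenile component (126.5 and 90.9).

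In juveniles 1 probe differed between FX40 and acetone in limma, a count that 3 of 35 splits of these arrays reached. DM08774P1 rose by 2.14 (SE 0.30, adjusted p = 0.0174, size uncertain near background), from -3.63 ± 0.33 (SD, n = 4) in acetone to -1.50 ± 0.58 (SD, n = 4), and it was well above background on 2 of 4 acetone arrays and 4 of 4 treated arrays. It was also among the probes called for FV10, in which its mean was -1.66 ± 0.38 (SD, n = 4). Its means in NP20 and NP60, where it was not called, were -2.4 ± 0.38 and -2.76 ± 0.28 (SD, n = 4 each). All values of these groups also lay above the highest acetone value (-3.34), so its values were higher in every treated juvenile group. The probe was picked with these same acetone arrays, so a difference in that direction is built in. In all, 1085 probes had an unadjusted p under 0.05, where 644 are expected by chance. The count was 0 with slide as a block, with brightness as a covariate, after normexp with quantile normalization, and when acetone C, acetone D, FX40 A, FX40 C or FX40 D was left out. DM08774P1 also missed the threshold after normexp correction (log2 change 0.42), where a different probe was called, and with only the 8 arrays of both groups. The count was 14 with these 8 arrays, 22 with array weights, 2 without acetone A, 2 without acetone B and 3 without FX40 B.

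The inhibitors were compared directly in each stage, at the doses the labels give (40 and 10 µg/L), which are not matched. Both compounds carry a trifluoromethylphenyl group, fluoxetine as an aryl ether of a propylamine and fluvoxamine as an oxime ether. In juveniles 2 probes differed. DM08363P1 was higher in FX40 than in FV10 by 2.05 (SE 0.30, adjusted p = 0.0125), at 6.04 ± 0.28 against 3.99 ± 0.11 (SD, n = 4 each), and DM09934P1 was lower, with a log2 difference of -5.95 (SE 0.82, adjusted p = 0.0121). For DM09934P1 it was -5.35 without FV10 A (adjusted p = 0.0594), -6.67 without FV10 C, -4.32 without both FV10 A and B (0.129) and -5.95 with the 8 arrays of both groups alone (0.0548). With single arrays left out, the difference of DM08363P1 ran from 1.93 to 2.14, and its adjusted p stayed under 0.05 in 5 of 8 fits. In all, 2216 of 12879 probes had an unadjusted p under 0.05. The median 95% half-width of a difference was 0.876 on the log2 scale, for a single test without adjustment. Simulation was not run for this comparison. For juvenile FV10 against acetone it gave calls, after adjustment, for 12% of probes changed by 1 and 58% of those changed by 2, so absence of a call does not show absence of a difference. The 1020 probes called for FV10 had a median change of 0.523 in the same direction in FX40, where 994 of them (97.5%) moved that way. They also moved that way in NP60 (887 probes, 87%, median 0.276) and in NP20 (809 probes, 79.3%, median 0.225). All these comparisons used the same acetone arrays, with which the probes were picked. A shift in that direction is therefore built in, and its size without any effect was not computed. Over all probes the correlation of the FX40 and FV10 log2 changes was 0.479, with a covariance of 0.257. Unchanged groups simulated against shared controls gave a median correlation of 0.498 and a mean covariance of 0.152, and 8 of 100 draws had a covariance as high. With the acetone arrays split 2 and 2, the correlation averaged 0.199, between 0.116 and 0.282. The direct comparison gave 884 calls without FV10 C and 6 without FV10 D, 4 without FX40 A, 1 without FX40 D, and 0 without FV10 A, without FX40 B or without both FV10 A and B. It gave 24 with the 8 arrays alone, 0 with slide as a block, 7 with brightness as a covariate and 620 after normexp with quantile normalization. In adults the same comparison called 0 probes in limma, with 1022 at an unadjusted p under 0.05 and a median half-width of 0.961. The adult count was 2 without FX40 B, 2 without FX40 G and 17 with array weights.

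Nonylphenol in juveniles left no probe past the threshold in limma. NP20 had 769 probes and NP60 696 probes at an unadjusted p under 0.05, where chance gives 644. The doses differed from each other at 0 probes, with 455 at an unadjusted p under 0.05. Without NP20 C, NP20 had 1 call, and NP60 had 2 without acetone B and 1 without its own array D. Array weights gave NP60 5 calls, testing all probes gave it 1, and normexp with quantile normalization gave it 11.

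In adults 48 of 12544 tested probes differed between FX40 and acetone in limma, 14 higher and 34 lower in FX40, all by at least 2-fold. Among called probes with 4 values in each group and no overlap between groups, DM08009P2 and DM09557P1 fell most, with log2 changes of -4.31 (SE 0.74, adjusted p = 0.0185) and -4.19 (SE 0.76, adjusted p = 0.0203). With normexp correction these were -2.53 and -2.35. With single arrays left out, DM08009P2 ran from -4.93 (without FX40 G) to -3.73 (without FX40 F) and DM09557P1 from -4.90 to -3.45 (the same arrays). DM08009P2 averaged -1.04 ± 1.63 in FX40 against 3.27 ± 1.00 in acetone (SD, n = 4 each), and the adult FV10, NP20 and NP60 groups had means of 3.26, 3.26 and 3.83. DM04537P4 and DM05642P3 rose by 2.23 (SE 0.45, adjusted p = 0.042) and 2.12 (SE 0.44, adjusted p = 0.0434), and each was well above background on 3 of 4 acetone arrays. These rises were not particular to FX40. DM04537P4 averaged -0.81 in FX40, -1.11 in FV10, -1.04 in NP20 and -0.9 in NP60, against -3.05 in acetone. For DM05642P3 the means were -0.79, -1.39, -1.78 and -1.49, against -2.9 in acetone. Calls of single probes depended on arrays. Without acetone B the adjusted p of DM08009P2 was 0.0655 and that of DM09557P1 0.0658, without acetone E 0.0792 and 0.1, and without FX40 B 0.0679 and 0.0804, and DM09557P1 reached 0.0668 without acetone F. DM04537P4 had 0.0547, 0.119 and 0.0538 without acetone B, E and F and 0.103, 0.0665 and 0.0592 without FX40 B, C and F. DM05642P3 had 0.0655 and 0.124 without acetone B and E and 0.0804, 0.116, 0.0618 and 0.0716 without FX40 B, C, F and G. Both rises turned into small falls after normexp correction with scaling to the 75th percentile, at -0.44 and -0.25. Non-overlapping values were found for 9 higher and 28 lower called probes, and for 7.48% of all probes, where chance gives 2.86%. The share of all probes was 6.98% in adult NP20, 4.81% in FV10 and 4.16% in NP60, each with 0 calls.

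The median change of the 48 probes in the FX40 direction was 0.828 in adult FV10, 1.03 in NP20 and 0.873 in NP60, and 48, 47 and 44 of them moved that way, although no probe was called there. These comparisons share the 4 acetone arrays, which were used to choose the probes, so a shift in that direction is built in and its size without any effect was not computed. The FX40 arrays were brighter than the acetone arrays, at a log2 75th percentile of 8.45 ± 0.34 against 7.38 ± 0.74 (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible, adjusted over 8 comparisons 0.229). With brightness as a covariate 0 probes were called, and the median change of the 48 went from 1.74 (median SE 0.324) to 1.52 (median SE 0.372). With slide as a block 0 were called and the median change was 1.69 (median SE 0.411). FX40 and acetone met on slides 3 and 4. When 48 probes were picked without the arrays of the slide, they differed within it by a median of 0.915 in the picked direction on slide 3 (85.1% of probes) and of 0.0365 on slide 4 (53.7%), against 1.92 and 1.95 in the arrays used to pick them. Without acetone B, E, F or G the count was 1, 1, 26 or 330, and without FX40 B, C or G it was 2, 20 or 30. Without both acetone E and G it was 0. With outlier spots kept it was 21, with the 8 arrays of both groups alone 0, and with array weights 996. Quantile normalization moved the median of all probes from 0.0455 to -0.0845 and gave 26 higher and 187 lower. Normexp correction moved it to -0.938 and gave 1228 higher and 6455 lower.

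**Figure D3:**
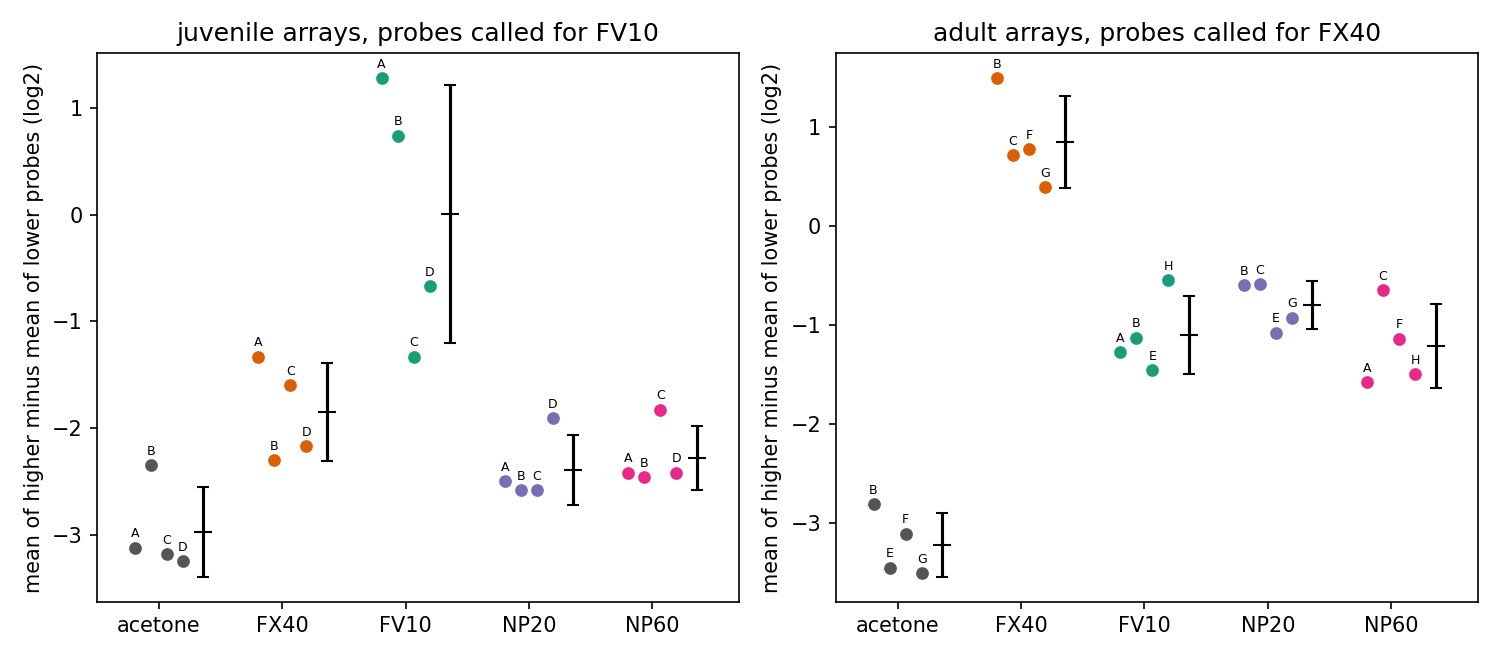
Mean scaled log2 signal of the probes called higher minus that of the probes called lower, for the 1020 probes of juvenile FV10 (left) and the 48 of adult FX40 (right); points are arrays with replicate letters, and bars give the mean and SD of 4 arrays. The acetone arrays had the lowest values of the adult plot, between -3.51 and -2.81, and the sets were chosen for the contrast between the treated group and acetone.

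The other adult treatments gave no call in limma with scaling to the 75th percentile. FV10 had 1017 probes, NP20 2006 and NP60 830 at an unadjusted p under 0.05, where chance gives 627, and the smallest adjusted p was 0.249, 0.0997 and 0.272. The nonylphenol doses differed at 0 probes, with 493 at an unadjusted p under 0.05 and 1 call without NP20 C. After normexp correction NP60 had 5603 calls (655 higher, 4948 lower), FV10 41 and NP20 1, and with array weights FV10 had 36 and NP60 6. NP20 had 146 calls without its array C, 104 without acetone G, 1 without acetone B, 1 without acetone E and 2 without acetone F, 95 (4 higher, 91 lower) after quantile normalization and 220 with array weights. The log2 changes of NP20 and NP60 against acetone correlated at 0.675, with a covariance of 0.351. Unchanged groups simulated against shared controls gave a median correlation of 0.504 and a mean covariance of 0.207, and 8 of 100 draws had a covariance as high. With the acetone arrays split the correlation averaged 0.189.

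Adults and juveniles without drug differed at 3396 of 13279 probes, 2056 higher in adults and 1340 higher in juveniles. DM08004P3 was higher in adults (adjusted p = 2.71e-20). No exact fold can be given, as it was saturated on all 4 adult arrays and well above background on 2 of 4 juvenile arrays. The log2 difference was 12.98 with scaling to the 75th percentile, 11.96 after quantile normalization, 11.63 with brightness as a covariate and 8.97 after normexp correction. DM02255P1 was also higher in adults (adjusted p = 7.15e-18), but it was saturated on 2 of 4 adult arrays and well above background on 3 of 4 juvenile arrays. DM07050P2 and DM06319P2 were higher in juveniles (adjusted p = 8.82e-06 and 4.31e-11), at 1.85 ± 0.87 and 2.24 ± 0.48 there (SD, n = 4 each). Each was well above background on 1 of 4 adult arrays, so no exact change can be given. The change was at least 2-fold for 1746 of the probes higher in adults and 1131 of those higher in juveniles. Stage, age, length of exposure to the carrier and removal of eggs went together in this design. The adult acetone arrays were also dimmer (7.38 against 8.88). With brightness as a covariate the count was 1448, and after normexp correction it was 724, with 149 higher and 575 lower in adults. The median of all probes moved from 0.161 to 0.722 with that correction, and with it DM07050P2 had a log2 change of -2.00 and missed the threshold, while DM06319P2 had -2.81 and passed it. With slide as a block it was 3075.

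Whether a treatment acted differently in the stages was tested as an interaction, which called 5 of 13278 probes by the F test over all 4 treatments, with 1505 at an unadjusted p under 0.05. Of 3 probes that fell in FX40 adults relative to juveniles, DM07014P1 and DM08009P2 had FX40 interaction terms of -7.55 (adjusted p of the F test 0.0239) and -4.35 (0.0149). DM07014P1 averaged -2.01 ± 3.61 (SD, n = 4) in FX40 adults and 5.82 ± 0.83 (SD, n = 3, a spot of array G left out as an outlier) in acetone adults, and 2.94 ± 0.72 and 3.22 ± 0.57 (SD, n = 4 each) in the corresponding juveniles. The FX40 adults were not alike. Arrays B, C and F lay between -4.38 and -3.26, while array G was at 3.36, below the lowest acetone value (5.27). DM11817P4 and DM00294P3 had positive terms for all 4 treatments. For FX40, FV10, NP20 and NP60 these were 2.24, 2.43, 1.69 and 2.18 in DM11817P4 (adjusted p of the F test 0.0361) and 1.62, 2.15, 1.30 and 1.14 in DM00294P3 (0.0232). The adult acetone means of these 2 probes, -1.03 (n = 3) and -2.26 (n = 4), lay below those of every treated adult group. These 4 were chosen after their values were seen. Tested singly, the FX40 term called 59 probes (12 above and 47 below the juvenile effect), the FV10 term 415 (176 above, 239 below), and the NP20 and NP60 terms 0 each, with 1240 and 724 at an unadjusted p under 0.05. These single-term counts were not rerun under the alternatives or with arrays left out. The F test count was 239 without juvenile FV10 C, 56 without adult acetone G, 48 without adult FX40 B, 47 without adult NP20 C, 13 without adult FX40 G, 12 without adult FX40 F, 10 without adult FV10 A, 9 without adult NP20 B and 9 without juvenile NP20 D. It was 3 without adult acetone B, adult acetone E, adult FX40 C, juvenile acetone A or juvenile acetone C, 2 without juvenile FX40 C and 0 without juvenile FX40 A. It was 54 after quantile normalization, 28 with the deposited log2 table, 383 with array weights and 3 with slide as a block.

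Across stages, which share no array, log2 changes against acetone of the same treatment correlated at 0.035 for FX40, 0.0145 for FV10, 0.175 for NP20 and 0.0961 for NP60, across probes, which are not independent replicates. Exact relabelling of the treated and acetone arrays in both stages (4900 relabellings) gave p = 0.784, 0.943, 0.238 and 0.521, and 0.943 for each after adjustment over 4. Of the 48 probes called for adult FX40 and 995 for juvenile FV10 among the 12344 tested in both, 10 were shared. All 10 went in opposite directions, 4 up in adults and down in juveniles (0.388 expected from independent lists) and 6 down in adults and up in juveniles (1.8 expected). The 1020 probes of juvenile FV10 ran mostly opposite in all 4 adult comparisons, which share the adult acetone arrays. Of the 995 tested, 18% went the same way in FX40, 31.4% in FV10, 19.3% in NP20 and 25.9% in NP60. Brightness differed in opposite directions too, the log2 75th percentile being 1.07 above acetone in adult FX40 and differing by -0.81 in juvenile FV10.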

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

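The covariate fit, the brightness slope over all 5 groups and slide as a random block were chosen after the result was seen. So was the fit without FV10 arrays A and B. The other tests here were set before the result was seen. Values on the scaled log2 axis are given as log2.

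In juvenile FV10, of the 35 splits of its 8 arrays into 4 and 4, only the real 1 called as many as 1020. That is the fewest this test can give. It was not adjusted over the counts tested, so the test alone does not exclude chance assignment of these arrays. The next split called 705, and it set FV10 A, B and D with acetone B, so it still contrasts most FV10 arrays with acetone, and the real comparison called 2481 without FV10 C but 3 or 2 without A or B. Whether array brightness is the whole cause is not decided. Its slope in the 3 other juvenile groups gave a share of 0.148 of the observed shift (95% interval -0.0922 to 0.387). Its slope over all 5 groups gave 0.253 (0.0408 to 0.466). FV10 A and B (log2 75th percentile 7.68) were dimmer than every array of those 3 groups (8.41 or more), so that slope was extrapolated. In FV10, the probes called higher minus those called lower averaged 1.28 and 0.74 on A and B. They averaged -1.33 on C (8.64) and -0.67 on D (8.26). Acetone C and D, near FV10 C in brightness (8.6 and 8.48), had -3.18 and -3.25. The probes were picked for this shift, which can make the shares too low. The covariate lowered the median change from 1.51 to 1.01, so a part may go with brightness. Slide stays open, since on the slides that held both groups, probes picked without those arrays gave ratios of 0.104 and 1.16 to the shift elsewhere, and an effect of fluvoxamine that differed between pools also stays open.

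The 48 probes of adult FX40 had 1 of 35 splits with as many calls, the fewest this test can give, and 6 in the next. This unadjusted test alone does not exclude chance assignment for these 48 probes. Brightness gave a share of 0.139 of their shift (95% interval 0.0652 to 0.212), or 0.102 (0.0216 to 0.182) with the slope over all 5 groups. Acetone E (6.27) was dimmer than every array of the 3 other adult groups (7.1 or more), so the slope was extrapolated for it. The other acetone arrays (7.74 to 7.77) lay within their range. The slopes argue against brightness as the whole cause, though a part may go with it (1.52 with the covariate against 1.74). The shift also depended on background handling. Its median was 0.66 after normexp correction, with 81.2% of probes keeping direction, and 1.71 after quantile normalization. These probes too were picked for their shift, which can make the shares too low. Slide stays open: probes picked without the arrays of a slide gave ratios of 0.476 on slide 3 and 0.0187 on slide 4, and each slide held a single array of each group. With slide as a block the median change of the 48 probes was 1.69 (median SE 0.411), against 1.74 (0.324), but 0 were called. Slide as a random block called 43. The 48 had been picked in the fit without slide. A peculiarity of the 4 acetone arrays was not tested apart from the treatment.

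The stage by treatment interaction called 5 probes, and 3 of 100 random reassignments of treatments within stages, the real one included, gave as many. This share was not adjusted over the counts tested, so chance is not firmly excluded. The highest of the others called 17. Tested singly, 59 probes differed between stages in their FX40 effect and 415 in their FV10 effect. The single terms were not adjusted over each other and were not rerun under the alternatives. Against acetone, adult FV10 had 0 calls, and the juvenile FV10 count of 1020 went to 3 or 2 without array A or B. How far the 415 rest on these arrays was therefore not tested. Stage also went together with age and length of exposure. For DM08009P2 the FX40 change in adults was below that in juveniles, the difference being -4.35 (adjusted p = 0.0148 over the FX40 term), and for DM09557P1 it was -3.75 (adjusted p = 0.0405).

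For the other counts, the comparison of acetone adults with acetone juveniles (3396) was reached by 1 of 35 splits, with 972 in the next. That is the fewest this test can give, again without adjustment over the counts tested. The single juvenile FX40 call was reached by 3 of 35 splits, with up to 11, and the 2 calls of juvenile FX40 against FV10 by 2 of 35, with up to 763, so chance is not excluded for either. The split with 763 put FX40 A with FV10 A, B and D, many times the real count, which points to a structure among the arrays; without FV10 C alone the real comparison called 884, so the split still contrasts the compounds in part. Comparisons with 0 calls were matched by 35 of 35 splits by definition, so the splits decide nothing for them. Their highest other counts were 1 for adult FV10, 79 for adult NP20, 2 for adult NP60, 31 for adult FX40 against FV10, 252 for adult NP60 against NP20, 2 for juvenile NP20, 0 for juvenile NP60 and 18 for juvenile NP60 against NP20. The adult split with 252 calls set NP20 C with NP60 A, F and H, against 0 for the real one, which points to a structure among the arrays whose nature was not tested.

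Single arrays lay far from the other 3 of their group in 11 of 178 groups examined, where chance gives about 1 in 20. Adult acetone E had a raw 75th percentile of 76.9, the others 213.6 to 217.7. Juvenile acetone C had 57.7% of probes well above background, the others 78.3% to 79.5%. Adult acetone G had 1379 spots with an outlier mark, the others 6 to 44, and juvenile FX40 C had 219, the others 6 to 25. DM05642P3 was at -0.24 in juvenile NP60 A (others 0.18 to 0.26), and DM09557P1 at 2.56 in juvenile acetone B (others 3.85 to 3.99). DM09934P1 was at 6.68 in adult FV10 A (others 0.21 to 0.55), and DM14640P2 at -1.23 in juvenile NP60 C (others at -2.47). DM08363P1 was at 4.59 in juvenile NP20 D (others 5.86 to 6.07). DM08004P3 was at 9.92 and DM02255P1 at 8.95 in adult acetone E, the dimmest array (others 8.18 to 8.26 and 7.75 to 7.86). DM08004P3 was saturated on all 4 of these arrays, so its scaled value is the scanner's ceiling minus the array's brightness, and DM02255P1 was saturated on 2 of 4.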

How the results depend on the processing

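Array weights, slide as a random block, brightness as a covariate, outlier spots kept, normexp with quantile normalization and the joint removals of 2 arrays were chosen after the result was seen. Where an alternative moved a count by more than 1.5 times the cause was not tested, unless named here. Normexp correction of the median signals with an offset of 50 called 7683 probes for adult FX40 against acetone, 41 for adult FV10, 1 for adult NP20, 5603 for adult NP60, 1 for juvenile FV10 and 724 between stages, and it reversed DM04537P4 (-0.44) and DM05642P3 (-0.25) in adult FX40. The offset weighs more on dim arrays by construction, and the median of all probes moved to -0.938 in adult FX40 and to 0.722 between stages. Normexp with quantile normalization gave 199 for adult FX40, 67 for adult NP20, 0 for juvenile FX40, 11 for juvenile NP60, 620 for juvenile FX40 against FV10 and 126 for the interaction. Quantile normalization gave 213 for adult FX40, including 47 of the 48, 95 for adult NP20 and 54 for the interaction; for juvenile FV10 it gave 977, of which 765 were shared with the 1020. The deposited log2 table gave 30 for adult FX40 (28 shared), 2 for adult FV10, 1 for adult NP20, 4 for juvenile FX40 against FV10 and 28 for the interaction. Testing all probes gave 1 for juvenile NP60. With only the 8 arrays compared, and so fewer degrees of freedom, the counts were 0 for adult FX40, 14 for juvenile FX40, 5 for juvenile FV10 and 24 for juvenile FX40 against FV10. Slide as a block gave 0 for adult FX40, 0 for juvenile FX40, 1 for juvenile FV10, 0 for juvenile FX40 against FV10 and 3 for the interaction, while slide as a random block moved no count by more than 1.5 times. The replicate letter as a block gave 0 for adult FX40, 3 for juvenile FX40, 1 for juvenile NP20, 0 for juvenile FX40 against FV10 and 2 for the interaction. The residuals of same-letter arrays correlated at a mean of 0.093 over 20 adult pairs, against -0.014 for other letters. Of these 20 pairs 9 lay over 0.1, with values down to -0.23, and 3 of 20 adult arrays were closest to their own letter. In juveniles the mean was 0.0034 over 40 pairs, against -0.00076, with values down to -0.34. Whether the letters mark a shared batch stays open in adults. For arrays on the same slide the mean was 0.02 over 23 adult pairs, against -0.0043 for other slides. In juveniles it was 0.015 over 19 same-slide pairs, against -0.0016. Values went down to -0.21 in adults and -0.4 in juveniles. These means are over all probes, so they do not settle the part of slide in the called sets. Array weights gave 996 for adult FX40, 36 for adult FV10, 220 for adult NP20, 6 for adult NP60, 17 for adult FX40 against FV10, 22 for juvenile FX40, 5 for juvenile NP60, 1 for juvenile FX40 against FV10 and 383 for the interaction. Brightness as a covariate gave 0 for adult FX40, 0 for juvenile FX40, 4 for juvenile FV10, 7 for juvenile FX40 against FV10 and 1448 between stages. Keeping outlier spots gave 21 for adult FX40. Without juvenile FV10 A and B the counts were 4 for juvenile FV10 and 0 for juvenile FX40 against FV10, and without adult acetone E and G they were 0 for adult FX40 and 3 for the interaction. With each array left out in turn, counts ran from 1 to 330 for adult FX40, 0 to 0 for adult FV10, 0 to 146 for adult NP20, 0 to 0 for adult NP60, 0 to 2 for adult FX40 against FV10, 0 to 1 for adult NP60 against NP20, 0 to 3 for juvenile FX40, 2 to 2481 for juvenile FV10, 0 to 1 for juvenile NP20, 0 to 2 for juvenile NP60, 0 to 884 for juvenile FX40 against FV10, 0 to 0 for juvenile NP60 against NP20, 2662 to 3466 between stages and 0 to 239 for the interaction. Of 306 alternative values of the named probes, 213 kept direction and side of the threshold, 91 kept the direction alone and 2 reversed. Not run were camera and fry, for want of gene names, the replicate block and the deposited table for the stage comparison, and the fit of only 2 groups, slide as a random block and brightness as a covariate for the interaction. Dim arrays limit what can be seen near background, as the share of probes well above it went down to 51.8% in adults and 57.7% in juveniles.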

Other observations

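The tests here were set before their results were seen. DM09934P1, the probe with the largest rise in juvenile FV10, was also high on some adult arrays, acetone arrays among them. It lay above 4 on 5 of 20 adult arrays, between 5.07 and 6.68, and at 2.14 or less on the other 15. The 5 were acetone B and E, FV10 A, FX40 B and NP20 C. In juveniles it lay above 4 on the 4 FV10 arrays alone. In adults the group means were 1.99 ± 4.17 in acetone and 1.99 ± 3.13 in FV10 (SD, n = 4 each), with no difference beyond the spread.

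A hypothesis was that a program varying between adults is the one shifted in juvenile FV10. The 100 probes that followed DM09934P1 most closely over the adult arrays within groups (absolute correlation 0.742 to 0.94, 24 positive and 76 negative) were scored in juveniles. Signed by that correlation, they shifted by a mean of 0.0011 on the log2 scale in FV10 against acetone (exact permutation p = 1), and 9 of them were called against 8.58 expected. Of the 100, 47 moved in the direction of their correlation. The values argue against these 100 probes shifting as a whole. A smaller set that varies with DM09934P1 stays open. DM06523P3, lower in juvenile FV10, was also lowest on the same 5 adult arrays, from -2.78 to -4.93, where the other 15 lay at -1.70 or higher. DM14198P1, also lower in juvenile FV10, was lowest on these 5 too, from -2.38 to 0.65, with the others at 0.70 or higher. DM14640P2 did not set these 5 apart from all other adult arrays. Within groups it was highest on them in acetone (-2.38 and -3.82, others -4.02 and -4.5), FX40 (-2.41) and NP20 (-0.6). In FV10, array B (-0.69) lay above A (-0.9). These relations were seen in the values and were not tested.

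A further hypothesis was that the inhibitors move animals along the axis from juvenile to adult expression. The juvenile FV10 calls overlapped with the stage difference (343 up in FV10 and higher in adults, 104 expected from independent lists), but both comparisons used the juvenile acetone arrays. The axis was therefore set by the nonylphenol arrays of both stages, on 11645 probes, on a scale where 1 is the full distance between stages. Juvenile FV10 lay at 0.164 ± 0.108 and acetone at 0.098 ± 0.067 (SD, n = 4 each; exact permutation p = 0.314, adjusted over 4 comparisons 0.495). Juvenile FX40 lay 0.042 below acetone (treated minus acetone -0.042, adjusted p = 0.495). Adult FV10 lay 0.126 above its acetone group (adjusted p = 0.495), and adult FX40 differed by -0.057 (adjusted p = 0.6). No shift passed the threshold, which does not show that there is none. Within groups, position along the axis correlated with brightness at -0.333 in juveniles and -0.436 in adults. These correlations were not tested, so a part played by brightness stays open.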
